A study of Mus musculus with 8 samples.

How the data were processed

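Tumours grown from B16F10 mouse melanoma cells under the skin of C57BL/6J mice were profiled by RNA-seq, 4 from mice on a normal diet (ND) and 4 from mice on a high cholesterol diet (HCD). Per the labels' protocols, total RNA was isolated with a Qiagen column kit, and paired-end libraries were made with the Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.9, HTSeq and edgeR and the genome build mm10, with no role or order given. The annotation release, the strand setting of the counting and other settings are not given in the sources used here. Per the file headers, each library has a column of counts, deposited as whole numbers per Ensembl gene with no normalization. It also has a column of FPKM, per the file headers, in which each count is divided by a gene length and by the library's total over the listed genes, as the values show.

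Samples were grouped by the diet in their labels, with the replicate number from the same label. The counts as deposited were tested, and the FPKM values served only to recover each gene's length. The files list 34745 genes, of which 34267 matched a gene name in GENCODE mouse M21 (GRCm38, the assembly also called mm10) and 478 did not and kept their identifiers. Coordinates and exon overlaps come from that annotation (bedtools 2.31.1). The number of genes with a count of 0 in all libraries was 11852. Total counts ran from 14599222 to 17722093 per library. Pairs of libraries within a group differed by 14.5 to 37.6 times the variance of sampling noise (chi-square per degree of freedom, over genes with a summed count of at least 20), so no library was a second sequencing of another one in its group. This does not tell separate tumours from separate libraries of the same tumour, and each library counted as 1 sample because the labels number them so.

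The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors and edgeR's expression filter (minimum count 10, minimum total 15), on all 8 libraries with diet as the only term. It ran on 13186 genes, which held at least 99.88% of each library's counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. CPM are TMM-normalized, and the common biological coefficient of variation was 17.2%. At an unadjusted p under 0.05, 1939 genes differed (951 higher and 988 lower in HCD), against 659 expected by chance. Adjusted p-values lay close together: 20 genes had an adjusted p from 0.05 to 0.06. Measures of single libraries were compared by two-sided exact permutation tests, for which 4 against 4 allows a smallest p of 0.0286.

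Before the data were examined, 30 gene lists with 554 symbols, the tests, the alternatives and the rule for named genes were fixed. Of the symbols, 3 matched no gene. Lists were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. List values per library are means over members of log2 CPM minus the gene's average over the 8 libraries. The rule named the 10 called genes with the largest change in each direction, among those with a mean of at least 1 CPM and non-overlapping groups; up to 4 members of each list with the smallest p; and genes fixed by name, among them Abca1, Pmel, Mki67, Cd8a and Adgre1. The 5 called genes beyond the first 10 that fell (Ndrg1, Kdm3a, Rps15a, Gm29216 and Gm28661) were added after their values were seen. This gave 140 genes. Single-gene results of 5 of them are not reported here, and every other one was carried through each alternative that tested it and the check for outlying libraries. The examples printed for a list are its members with the smallest p, in that order and apart from those not reported, plus genes fixed by name. A further 14 genes (Cry2, Dbp, Per1, Arntl, Cry1, Eif4ebp1, Pck2, Hells, Uhrf1, Chordc1, Ahsa1, Tsc22d3, mt-Co1 and mt-Nd1) and 7 further lists were chosen after their values were seen.

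The fit was tested on simulated counts for the 13186 genes of the HCD against ND comparison, with the real means, library sizes and spread. It called 34 of 67 genes changed 1.5-fold (50.7%), 49 of 67 changed 2-fold (73.1%) and 62 of 66 changed 4-fold (93.9%). There were 9 false calls, and 0 unchanged lists were called. The simulated genes were drawn independently, while estimated correlations in the real lists reached 0.946. The simulation therefore does not test false calls of lists whose genes move together. In this simulation, changes of 1.5-fold were missed about as often as found at this depth and number of libraries. Its planted 2-fold and 4-fold changes loosen the adjusted threshold, so the real comparison, with 24 called genes, may miss more of them.

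Alternatives fixed beforehand were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 1 CPM, thresholds of 0.01 or of a 2-fold change, the replicate number as a block, and each library left out. Alternatives added after seeing the data were robust dispersion moderation, a threshold of 0.10, a term for the 3 ND libraries with more detected genes, removal of mitochondrial genes and their nuclear copies, and offsets for GC content and gene length (GC content was known for 99.67% of tested genes). Nuclear copies of mitochondrial genes were found by BLAST 2.17.0 against the mitochondrial genes, at 90% identity or more over 50% of the copy or more, which gave 11 genes, 10 of them tested. No human samples were used and no sample was left out of the main test.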

Results

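RNA-seq was carried out on 8 tumour samples grown from B16F10 cells, a mouse melanoma line, placed under the skin of C57BL/6J mice. The mice received either a normal diet (ND, 4 samples, called ND 1 to ND 4) or a high cholesterol diet (HCD, 4 samples, called HCD 1 to HCD 4). The total count per library ranged from 14599222 in ND 4 to 17722093 in HCD 4. The group means were 16.4 ± 1.3 M counts for ND and 16.8 ± 0.767 M counts for HCD (SD, n = 4 each; two-sided exact permutation p = 0.714). The labels do not say whether the tumours came from separate mice, so p-values measure only the spread between these samples, which may be technical. The comparison of the 2 groups asks which tumour transcripts differ with the cholesterol content of the diet.

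Tumours of the HCD group had 9 genes that rose and 15 that fell among 13186 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p from 0.01 to 0.0495). The genes that rose included Cdc6, which loads the replicative helicase at replication origins, and Mitf, a transcription factor that governs the melanocyte lineage. The genes that fell included the stress-induced pseudokinase gene Trib3, the stress-induced transcription factor gene Ddit3, the hypoxia-inducible gene Ndrg1 and the circadian clock gene Per2. Among gene groups, all 24 tested cholesterol synthesis genes were lower in HCD and 28 of 29 cell cycle genes were higher, with camera adjusted p = 3.67e-10 and 6.31e-07 under a preset inter-gene correlation. Both lists had an adjusted p = 0.515 with an estimated correlation.

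Cdc6 (ENSMUSG00000017499, chromosome 11, 98907801 to 98923940, mm10) rose from 17.2 ± 0.429 CPM (TMM-normalized) in ND to 31.1 ± 1.43 CPM in HCD (SD, n = 4 each here and throughout), a log2 fold change of 0.85 (SE 0.0799, adjusted p = 0.01). Mitf (ENSMUSG00000035158, chromosome 6, 97807052 to 98021349) rose from 250.5 ± 34.3 to 452.6 ± 51.3 CPM, a log2 fold change of 0.85 (SE 0.112, adjusted p = 0.0459). Genes of DNA repair and recombination were among the others: Rad54l rose from 18.2 ± 0.901 to 26.9 ± 1.51 CPM, Recql5 from 19.1 ± 0.752 to 27.5 ± 0.938 CPM and Mlh3 from 12.4 ± 0.893 to 19.0 ± 0.924 CPM (adjusted p = 0.0459 for each). Trmt1l, related to a tRNA methyltransferase, had the largest rise, from 10.7 ± 2.4 to 22.0 ± 1.35 CPM (log2 fold change 1.04). Gemin4, the sialyltransferase gene St3gal1 and the phospholipase gene Pla2g6 completed the 9, with log2 fold changes of 0.59, 0.50 and 0.43.

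Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) fell from 154 ± 24 CPM in ND to 79.0 ± 2.76 CPM in HCD, a log2 fold change of -0.96 (SE 0.107, adjusted p = 0.0225). Ndrg1 (ENSMUSG00000005125, chromosome 15, 66929318 to 66969640) fell from 354 ± 18.5 to 239 ± 14.5 CPM, a log2 fold change of -0.57 (SE 0.0658, adjusted p = 0.0225). Ddit3 (ENSMUSG00000025408, chromosome 10, 127290774 to 127296288) fell from 84.4 ± 12.5 to 52.4 ± 1.52 CPM (log2 fold change -0.69, SE 0.104, adjusted p = 0.0459). Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) fell from 5.66 ± 1.3 to 1.83 ± 0.415 CPM (log2 fold change -1.62, SE 0.242, adjusted p = 0.0459). Osgin1, an oxidative stress response gene, fell from 34.8 ± 12.5 to 11.7 ± 2.22 CPM, and Il20rb, a cytokine receptor gene, from 4.07 ± 0.554 to 1.25 ± 0.343 CPM. Sgk1, a kinase gene induced by glucocorticoids, fell from 15.2 ± 0.759 to 8.17 ± 1.55 CPM. Log2 fold changes of the other protein-coding genes that fell were -0.80 for Cuedc1, -0.61 for the splicing factor gene Srsf5, -0.48 for the histone demethylase gene Kdm3a and -0.39 for the ribosomal protein gene Rps15a.

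The other 4 genes that fell, Gm10222, Gm28439, Gm29216 and Gm28661, are nuclear copies of mitochondrial genes on chromosome 1, at least 99.793% identical to their mitochondrial parents. Their log2 fold changes of -0.62, -0.62, -0.53 and -0.56 are therefore uncertain, since reads can be shared with the parents. Rps15a, which has processed pseudogenes, is uncertain in the same way. Of the 20 other called genes, 6 (Trmt1l, Gemin4, Rad54l, Recql5, Ddit3 and Ndrg1) share exon positions with another annotated gene, and the strand setting of the counting is not given in the sources used here, so reads of the overlapping genes may be mixed. All 4 HCD values lay on one side of all 4 ND values for each of the 24 genes. That separation held for 1275 tested genes, or 9.67%, against 2.86% by chance.

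Each of the 24 genes kept its direction when any library was left out, with log2 fold changes that moved by at most 0.28 (without ND 3). Since the groups do not overlap for any of the 24, a direction could hardly turn in this or the other fits. A kept direction therefore adds no support. The number of called genes was 7 without ND 1, 12 without ND 2, 2 without ND 3, 1 without HCD 1, 3 without HCD 2 and 2 without HCD 3. It was 0 without ND 4 or HCD 4, where edgeR gave 1603 and 1516 genes at an unadjusted p under 0.05. On all 8 libraries DESeq2 called 428 genes, among them all 24, and limma-voom called 19. Offsets for GC content and gene length, chosen after seeing the data, gave 4 higher and 12 lower genes in place of 9 and 15. Of the 24 genes 12 stayed called with these offsets, and all 24 kept their direction with log2 fold changes that moved by at most 0.0803.

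**Figure D1:**
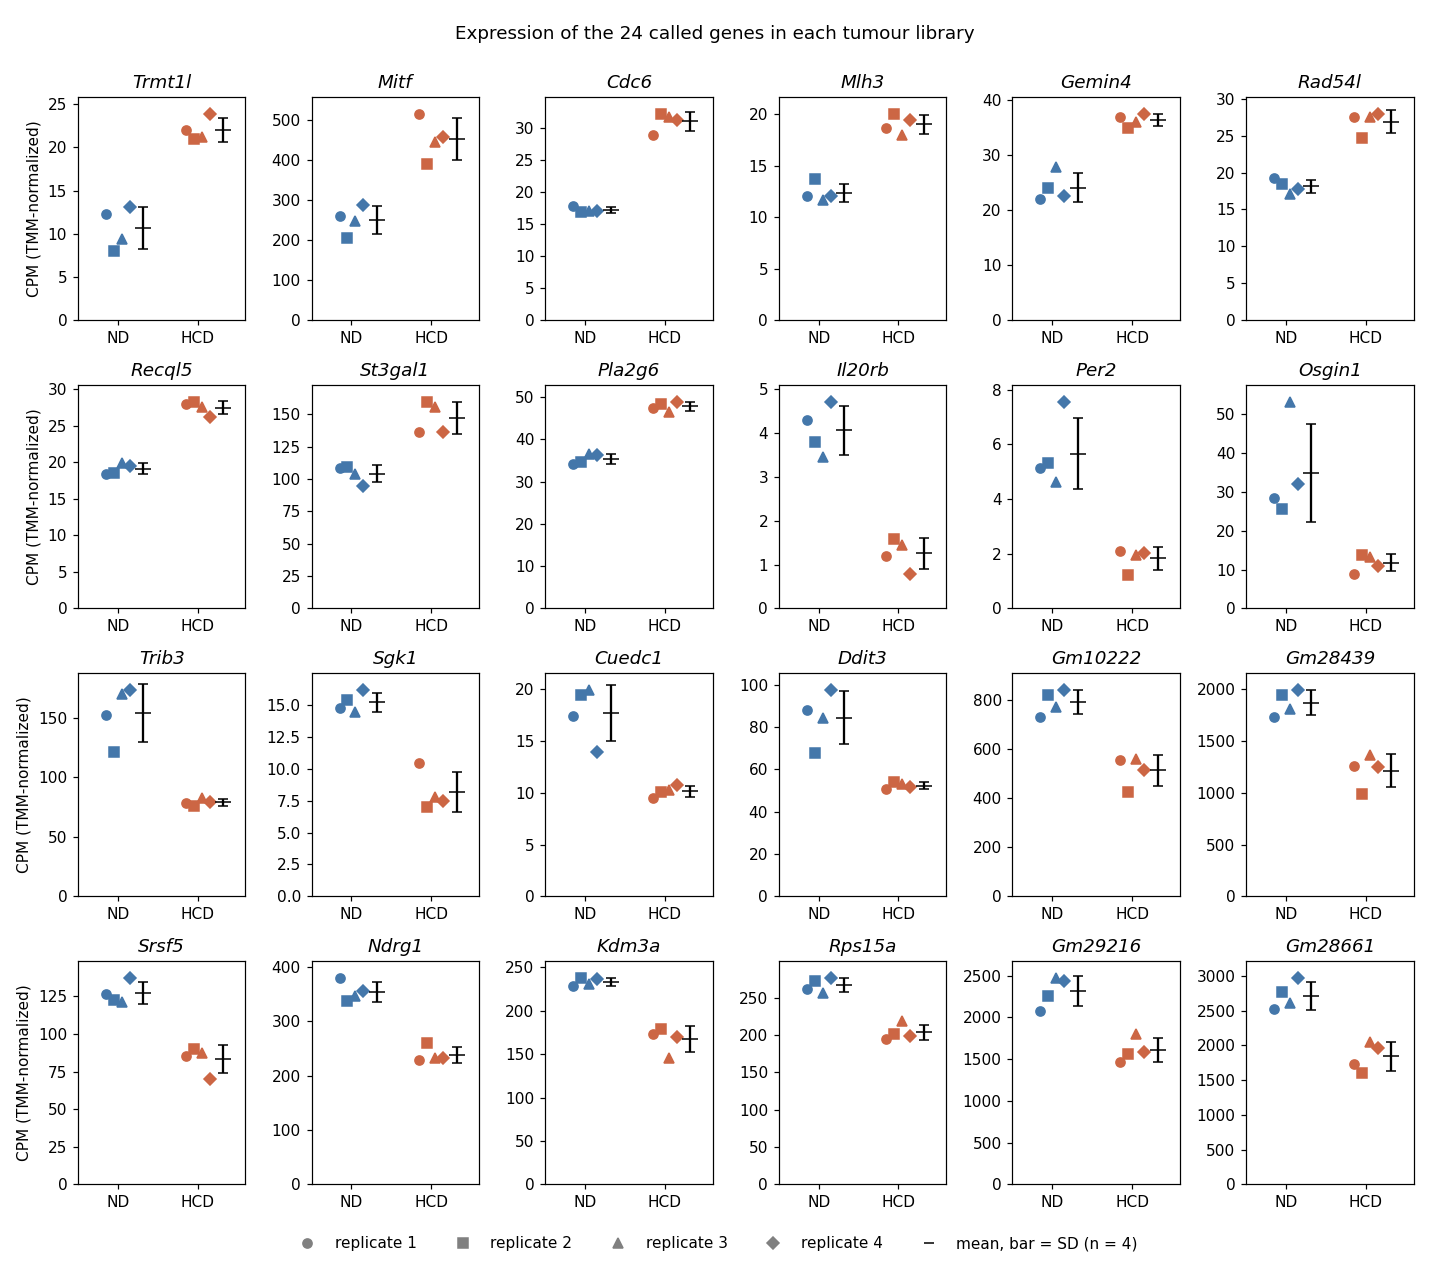
TMM-normalized CPM (vertical axes, from 0) of the 24 genes that passed the test, in each of the 4 ND (blue) and 4 HCD (orange) libraries. Marker shapes give the replicate number, and the black mark and bar are the mean and SD (n = 4). In each panel all 4 HCD values lie above or all 4 lie below the ND values, as for Cdc6 at 17.2 ± 0.429 against 31.1 ± 1.43 CPM.

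Libraries differed in ways that moved partly with diet. ND 2, ND 3 and ND 4 had counts on 18224, 18175 and 18088 genes, while ND 1 had 16745 and the HCD libraries 16285 to 16728. Olfactory and vomeronasal receptor genes, which are expressed in sensory epithelia, had at least 1 count for 438 to 465 genes in ND 2 to ND 4 and for 8 to 13 genes in the other 5 libraries. Mitochondrially encoded genes took 14.0 ± 0.48% of counts in ND and 12.2 ± 0.719% in HCD (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). ND 2 stood apart on the first principal component, which held 28.3% of the variance, at 53.2 against -18.8 to 4.93 for the other 7 libraries. A fit with a term for ND 2 to ND 4, chosen after seeing the data, rested the diet contrast on ND 1 against the 4 HCD libraries, with this lone ND library assumed to vary like the others. It called 5 genes, none of them among the 24, with 1484 genes at an unadjusted p under 0.05. A kept direction of all 24 genes adds no support here either, since ND 1 lies apart from every HCD value for each of these genes. Their log2 fold changes were 0.708 (Gm29216) to 1.23 (Gemin4) times those without the term, and the SE rose by a median of 1.58 times. Mitf moved from 0.85 to 0.79, Ddit3 from -0.69 to -0.75 and Per2 from -1.62 to -1.49. Without mitochondrial genes and their nuclear copies, 4 genes were called, while the log2 fold changes of the 20 other called genes moved by at most 0.0037. Adjusting the p-values of the first fit anew without these genes was enough to end 17 of the 20 calls.

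**Figure D2:**
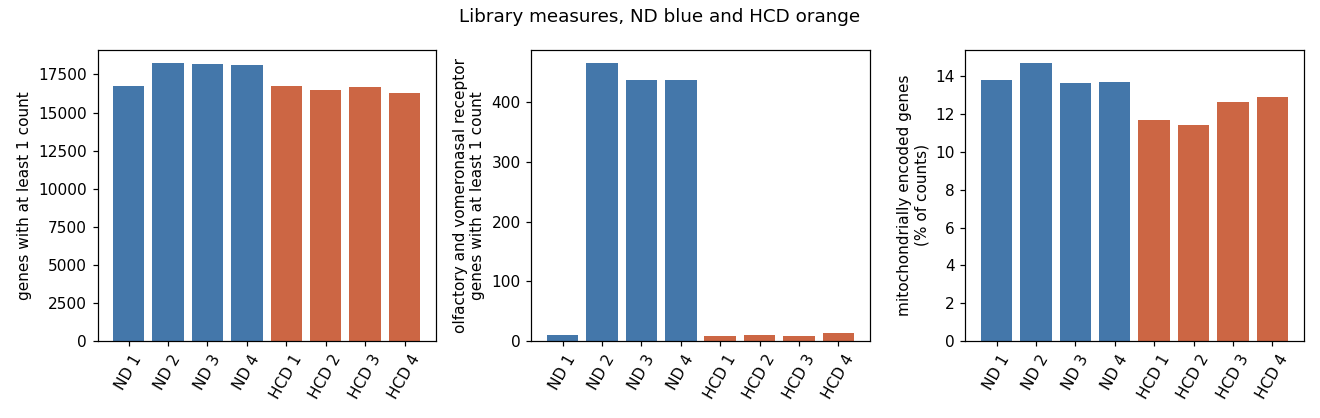
Number of genes with at least 1 count, number of olfactory and vomeronasal receptor genes with at least 1 count, and percent of counts on mitochondrially encoded genes, with 1 bar per library (ND blue, HCD orange, axes from 0). ND 2, ND 3 and ND 4 show 438 to 465 receptor genes and the other 5 libraries 8 to 13, and the mitochondrial share runs from 11.4% in HCD 2 to 14.7% in ND 2.

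Genes of cholesterol synthesis, which sterol-sensing transcription factors induce when cell cholesterol is low, were lower in HCD in all 24 tested members, with a median log2 fold change of -0.27. Adjusted over the list alone, 14 genes passed, and over all genes tested 0 did, with 15 genes at an unadjusted p under 0.05 (edgeR; DESeq2 called 7 over all genes and limma-voom 0). Fdps, an enzyme of isoprenoid synthesis, was at 203 ± 15.1 CPM in ND and 157 ± 9.12 CPM in HCD (log2 fold change -0.38, adjusted p = 0.00384 over the list alone and 0.0723 over all genes). Tm7sf2, a sterol reductase whose exons overlap those of Vps51, was at 21.1 ± 1.56 and 14.4 ± 1.92 CPM (log2 fold change -0.55, 0.00487 over the list alone and 0.0873 over all genes). The mean deviation of the list from each gene's average over all libraries was 0.0161 to 0.326 on the log2 scale in the ND libraries and -0.311 to -0.0253 in the HCD libraries. The camera adjusted p was 3.67e-10, against an adjusted p = 0.515 with an estimated correlation. The count over the list alone was 9 without ND 1, 9 without ND 2, 6 without HCD 1 and 6 without HCD 2. With the term for ND 2 to ND 4 it was 0 (edgeR), while 23 of the 24 genes were lower and the camera call held.

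Targets of LXR, the nuclear receptors that sense oxysterols, were higher in 9 of 12 tested members, with a median log2 fold change of 0.27 (camera adjusted p = 0.025, and adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 2 genes passed, and over all genes tested 0, with 4 at an unadjusted p under 0.05 (edgeR; DESeq2 called 2 and limma-voom 0). They were Lpl, lipoprotein lipase, at 6.65 ± 2.3 CPM in ND and 15 ± 1.87 CPM in HCD, and Abca1, a cholesterol exporter, at 40.2 ± 6.51 and 66.7 ± 13.3 CPM (adjusted p = 0.0723 and 0.099 over all genes). The call was lost without HCD 3 (adjusted p = 0.103) and with the term for ND 2 to ND 4 (0.402), and the count over the list alone was 4 without ND 1 and 0 with the term, where the median was 0.15. ND 2 had the lowest list value, -0.53, against -0.14 to 0.022 in the other ND libraries. Macrophage genes, whose median log2 fold change was 0.50, also had their lowest list value in ND 2 (-0.81) and their highest in HCD 3 (0.55, against 0.301 for the LXR list), so the LXR change is not separated from macrophage content. The list of cholesterol uptake, storage and oxidation had 6 higher and 7 lower members and 0 passing over the list alone or over all genes in edgeR, with 6 members at an unadjusted p under 0.05, 3 in each direction (camera adjusted p = 0.771). DESeq2 passed 5 members over the list alone (3 higher) and 0 over all genes, and limma-voom 3 (2 higher) and 0. Without ND 1, 4 higher and 2 lower members passed over the list alone, without ND 3 1 higher and without HCD 1 1 lower. With no expression filter 3 higher and 2 lower members did, with robust dispersion 2 and 1, and with upper-quartile factors 1 and 1. Members higher were 8 of 13 without ND 1 and 7 without ND 4, HCD 1 or HCD 4 or with no filter. Its median log2 fold change was -0.00374, while its mean, 0.149, and its test pointed up. Nceh1, a cholesterol ester hydrolase, was at 95.7 ± 10.2 and 117 ± 7.89 CPM, and Vldlr, a lipoprotein receptor, at 55.0 ± 7.83 and 41.0 ± 6.46 CPM. Fatty acid synthesis genes were higher in 7 and lower in 8 members (camera adjusted p = 0.704), with the desaturase gene Fads1 the only member passing over the list alone, at 326 ± 15.7 and 242 ± 26.9 CPM. Over all genes 0 passed, with 2 at an unadjusted p under 0.05 (edgeR; DESeq2 called 1 and limma-voom 0), and Fads1 no longer passed over the list alone with the term. Members higher were 9 of 15 without ND 2 or with the term and 8 without HCD 2.

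Cell cycle genes were higher in HCD in 28 of 29 members, with a median log2 fold change of 0.15 (camera adjusted p = 6.31e-07, and adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 6 passed, and over all genes tested 1, Cdc6. Bub1b, a spindle checkpoint kinase, was at 80.6 ± 3.9 CPM in ND and 97.4 ± 6.14 CPM in HCD (log2 fold change 0.27), and Mcm4, a subunit of the replicative helicase, at 57.8 ± 1.74 and 70.5 ± 7.49 CPM (0.29). Mki67, a proliferation marker, was the only lower member, at 366 ± 101 and 326 ± 16.1 CPM (log2 fold change -0.17, adjusted p = 0.712). The count over the list alone was 2 without ND 1, 3 without ND 2, 1 without ND 3, 1 without ND 4, 1 without HCD 1, 3 without HCD 2, 1 without HCD 4, 1 with the term for ND 2 to ND 4 and 1 with GC and length offsets. The median was 0.096 without HCD 4. The camera call held in each of these fits except that with GC and length offsets, where camera was not run.

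Melanocyte lineage genes were higher in 12 and lower in 6 of 18 members, and the list did not pass (camera adjusted p = 0.0701). Mitf was the 1 member that rose, over the list alone and over all genes. Slc24a5, a melanosome ion exchanger, was at 279 ± 27.2 CPM in ND and 331 ± 35.9 CPM in HCD, and Pmel, a melanosome matrix protein, at 9194 ± 967 and 8482 ± 573 CPM (log2 fold change -0.12, adjusted p = 0.588). The list passed without ND 3 (adjusted p = 0.0291) and without HCD 1 (0.036), where 2 genes passed over the list alone. Mesenchymal and invasion genes were higher in 14 and lower in 5 members (camera adjusted p = 0.344), with 0 passing over the list alone or over all genes and 0 at an unadjusted p under 0.05 by edgeR, DESeq2 or limma-voom. With the term for ND 2 to ND 4, 4 mesenchymal genes were higher and 15 lower, and without ND 2 10 were higher and 9 lower. The median of 0.13 became -0.18 with the term, 0.306 without ND 1, 0.0114 without ND 2, 0.0504 without ND 4 and 0.0478 without HCD 3. The list value was lowest in ND 4 in the ND group and in HCD 4 in the HCD group (-0.41 and -0.22), as was that of the fibroblast list (-0.99 and -0.78), so fibroblast content is not separated from it. Spp1, osteopontin, was at 29.6 ± 8.05 and 22.2 ± 6.46 CPM, and the membrane protease gene Mmp14 at 252 ± 21.8 and 276 ± 16.9 CPM.

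Genes of hypoxia and glycolysis were lower in HCD in 21 of 23 members, with a median log2 fold change of -0.20 (camera adjusted p = 1.88e-05, and adjusted p = 0.515 with an estimated correlation). Ndrg1 was the 1 gene passing over the list alone and over all genes tested. Vegfa, the angiogenic growth factor, was at 87.2 ± 8.18 CPM in ND and 70.2 ± 6.28 CPM in HCD (log2 fold change -0.31), and Egln1, an oxygen-sensing hydroxylase, at 309 ± 19.6 and 268 ± 17 CPM (-0.20). The count over the list alone was 4 without ND 3 and 8 without HCD 2. Nuclear genes of oxidative phosphorylation were lower in 31 of 39 members, with a median of -0.073 (camera adjusted p = 0.0178, and adjusted p = 0.515 with an estimated correlation). Ndufb5, a complex I subunit, was the 1 member passing over the list alone, at 66.5 ± 11.3 and 44.9 ± 2.61 CPM, and 0 passed over all genes tested, with 5 at an unadjusted p under 0.05 (edgeR; DESeq2 called 1 and limma-voom 0). Its exons overlap those of Mrpl47. The call was lost without ND 2 (adjusted p = 0.0519), without HCD 1 (0.151) and with the term for ND 2 to ND 4 (0.121). Skeletal muscle genes were also lower in HCD, with the limits given for that list below. The values of both lists ran in the same order in the ND libraries, highest in ND 2 (0.0681 for oxidative phosphorylation, 2.08 for muscle) and lowest in ND 4 (0.00998 and -0.71). Both were highest in HCD 3 among the HCD libraries (0.0203 and -0.18). HCD 4 came next for oxidative phosphorylation (-0.0144) but was lowest for muscle (-1.01). Ndufb5, at 76.95, 72.87, 64.76 and 51.22 CPM in ND 1 to ND 4, was highest in ND 1, while muscle was highest in ND 2. Acta1, skeletal muscle actin, was at 9.01 CPM in ND and 0.552 CPM in HCD, against 66.5 and 44.9 CPM for Ndufb5. The shared orders therefore do not show muscle content as the source of the change in oxidative phosphorylation, and they do not exclude it. The count over the list alone was 0 without each of ND 1, ND 2, ND 3, HCD 1, HCD 2, HCD 3 and HCD 4.

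Unfolded protein response genes were higher in 9 and lower in 12 of 21 members, and the list did not pass (camera adjusted p = 0.173). Adjusted over the list alone, 5 were lower, and over all genes tested 2, Trib3 and Ddit3. Chac1, which degrades glutathione, was at 28.5 ± 5.04 CPM in ND and 18.8 ± 2.09 CPM in HCD, and Atf4, the transcription factor of the integrated stress response, at 436 ± 39.6 and 327 ± 41.2 CPM (log2 fold changes -0.60 and -0.42). The list passed without ND 2 (adjusted p = 0.0489), and 2 genes passed over the list alone with the term for ND 2 to ND 4. Members higher were 12 of 21 without ND 4 or HCD 1 and 11 without HCD 3. Immediate early and heat shock genes were higher in 7 and lower in 9 members (camera adjusted p = 0.119), with 1 higher and 4 lower over the list alone and 0 over all genes, where 7 had an unadjusted p under 0.05 (edgeR; DESeq2 called 3 and limma-voom 0). Hsph1, a chaperone, was at 32.8 ± 2.81 and 49.97 ± 5.44 CPM, while Atf3, a stress-induced transcription factor, was at 25.7 ± 5.38 and 16.7 ± 2.01 CPM (adjusted p = 0.0506 and 0.122 over all genes). The count of lower genes over the list alone was 7 without ND 2, where the list passed (adjusted p = 0.0256), 2 without HCD 2 or HCD 3, 1 with the term, and 0 without ND 1, ND 4 or HCD 1. Over all genes edgeR called 1 higher gene with no filter, at a mean of at least 1 CPM or with robust dispersion.

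Targets of the oxidative stress factor NRF2 were higher in 5 and lower in 11 members (camera adjusted p = 0.119), and Osgin1 was the 1 gene passing, over the list alone and over all genes. Slc7a11, the cystine importer, was at 40.0 ± 14.6 CPM in ND and 22.9 ± 4.39 CPM in HCD. Without ND 2 the list passed (adjusted p = 0.0372), with 2 genes over the list alone, while without ND 4 8 members were higher and 8 lower. With GC and length offsets 3 genes passed over the list alone, and with the term for ND 2 to ND 4 1 higher and 1 lower did. Targets of p53 were higher in 4 and lower in 10 members (camera adjusted p = 0.0825). Bbc3, a mediator of apoptosis, was the 1 member passing over the list alone, at 9.95 ± 1.66 and 5.92 ± 0.886 CPM, and Mdm2 was at 77.3 ± 6.64 and 67.7 ± 4.45 CPM. Over all genes 0 passed, with 2 at an unadjusted p under 0.05 (edgeR; DESeq2 called 1 and limma-voom 0). That list passed without ND 4 (adjusted p = 0.0142, with 2 genes over the list alone) and without HCD 1 or HCD 4 (0.0313 each). However, 0 genes passed over the list alone without HCD 2, HCD 3 or HCD 4, with the term for ND 2 to ND 4 or with GC and length offsets.

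Macrophage genes were higher in HCD in 17 of 18 members, with a median log2 fold change of 0.50 (camera adjusted p = 3.22e-05, and adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 2 passed, and over all genes tested 0, with 5 at an unadjusted p under 0.05 (edgeR; DESeq2 called 2 and limma-voom 0). Mrc1, a mannose receptor, was at 9.05 ± 1.96 CPM in ND and 20.3 ± 4.37 CPM in HCD (log2 fold change 1.17, adjusted p = 0.0506 over all genes), and Ccr2, a chemokine receptor of monocytes, at 1.66 ± 0.661 and 3.77 ± 0.434 CPM (1.18, 0.128). Adgre1, which encodes F4/80, was at 8.22 ± 2.37 and 12.4 ± 2.32 CPM (0.59, 0.271). The list value was -0.81 in ND 2, -0.48 in ND 3, -0.18 in ND 4 and 0.24 in ND 1, against 0.11 to 0.55 in the HCD libraries. The median was 0.302 without ND 2 and 0.0116 with the term for ND 2 to ND 4, where 9 genes were higher, 9 were lower and the call was lost (adjusted p = 0.824). The count over the list alone was 9 without ND 1, 7 with no expression filter, 1 without HCD 1, HCD 2 or HCD 3, and 0 with the term. Over all genes edgeR called 1 member with no filter, at a mean of at least 1 CPM or with robust dispersion.

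Type I interferon genes were higher in 21 of 24 members and genes of antigen presentation and the interferon gamma response in 18 of 24 (camera adjusted p = 0.025 and 0.0281, and adjusted p = 0.722 for both with an estimated correlation). Over the list alone and over all genes 0 passed by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 in edgeR. The medians were 0.16 and 0.20. ND 2 lay far below the rest, with list values of -2.1 and -2.09, against 0.108 to 0.47 and -0.00768 to 0.653 in the other 7 libraries. Oas2, an antiviral enzyme, was at 2.22 ± 1.33 CPM in ND and 4.38 ± 0.555 CPM in HCD, and H2-Ab1, a class II antigen-presenting chain, at 45.8 ± 27.1 and 69.5 ± 15.4 CPM. Without ND 2 both lists turned down, with adjusted p = 0.122 for interferon and 0.0489 for antigen presentation, and both turned down with the term for ND 2 to ND 4 (0.578 and 0.293), where H2-Ab1 also changed sign. The interferon call was lost without HCD 2 (0.0517) or HCD 3 (0.096), and the antigen presentation call without HCD 1 (0.0881) or HCD 3 (0.106). The interferon median was 0.351 without ND 1, -0.17 without ND 2, 0.264 without ND 3, 0.4 without ND 4, 0.247 without HCD 4 and -0.14 with the term. The antigen presentation median was 0.394 without ND 1, -0.12 without ND 2, 0.109 without HCD 1 and -0.43 with the term.

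No lymphocyte, granulocyte or dendritic cell list passed. Many of their genes did not pass the expression filter, and members here are the tested ones. Tested were 10 of 19 T cell, 6 of 17 cytotoxic and NK, 9 of 14 checkpoint and 3 of 13 B cell genes. Of dendritic cell genes 8 of 12 were tested, of neutrophil genes 5 of 15 and of inflammatory genes 12 of 20. T cell genes were higher in 9 of 10 members (camera adjusted p = 0.199), cytotoxic and NK genes in 5 of 6 (0.344) and checkpoint genes in 7 of 9 (0.246). B cell genes were higher in 3 of 3 (0.0655) and dendritic cell genes in 5 of 8 (0.196), while neutrophil genes were lower in 4 of 5 (0.614). Without ND 2, the higher members were 5 of 10 T cell, 2 of 6 cytotoxic and 2 of 9 checkpoint genes, and with the term for ND 2 to ND 4 they were 3, 3 and 1. Cytotoxic genes were higher in 3 of 6 without HCD 2, dendritic cell genes in 4 of 8 without ND 3 or with the term, and neutrophil genes in 3 of 5 without ND 3 or by limma-voom. Cd8a, a cytotoxic T cell marker, was at 1.42 ± 0.805 CPM in ND and 1.58 ± 0.312 CPM in HCD (log2 fold change 0.14, adjusted p = 0.917). Il2rb, a cytokine receptor chain, was at 2.41 ± 1.51 and 3.23 ± 0.882 CPM, Nkg7 at 1.10 ± 0.547 and 1.62 ± 0.553 CPM, Entpd1 at 7.30 ± 1.45 and 9.80 ± 0.551 CPM, and Cd22 at 1.14 ± 0.757 and 2.27 ± 0.382 CPM. Clec10a was at 1.23 ± 0.718 and 2.23 ± 0.58 CPM, and Hdc at 1.07 ± 0.783 and 0.467 ± 0.184 CPM. Inflammatory cytokine genes were higher in 5 and lower in 7 members (camera adjusted p = 0.818), with a median of -0.223 and a mean of -0.159 but an upward test. It had 8 higher and 4 lower without ND 3, 9 and 3 by limma-voom (median 0.156), 6 and 6 without ND 1, and 5 and 4 at a mean of at least 1 CPM. The median was 0.151 without ND 3 and -0.013 without ND 1. Nfkbia, an NF-kappaB inhibitor, was the 1 member passing over the list alone, at 28.9 ± 2.64 and 20.5 ± 2.8 CPM, and Ccl7 was at 3.10 ± 1.58 and 6.08 ± 1.69 CPM. Nfkbia no longer passed over the list alone without ND 3, ND 4 or HCD 4 or with the term for ND 2 to ND 4. Over all genes 0 members of these 7 lists passed in edgeR or limma-voom, and DESeq2 called 1, in the inflammatory list. At an unadjusted p under 0.05 edgeR had 1 checkpoint, 1 B cell and 2 inflammatory genes. ND 2 had the lowest value of the 8 libraries in each of these 7 lists, from -1.68 for the cytotoxic list to -0.61 for dendritic cells. Without ND 1 the T cell (adjusted p = 0.0402), checkpoint (0.0323) and B cell (0.0086) lists passed, B cells also without ND 4 (0.0363). Over the list alone 1 checkpoint and 2 B cell genes passed without ND 1. Without ND 2, 1 checkpoint gene passed downward over the list alone, the neutrophil list passed downward (0.0489) and Cd8a changed sign, as Cd8a and Il2rb did with the term for ND 2 to ND 4.

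Fibroblast and matrix genes were higher in all 18 tested members, with a median log2 fold change of 0.52 (camera adjusted p = 0.0127, and adjusted p = 0.674 with an estimated correlation). Over the list alone and over all genes 0 passed by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 in edgeR. Fbn1, fibrillin, was at 11.1 ± 4.1 CPM in ND and 16.6 ± 5.45 CPM in HCD, and Bgn, a matrix proteoglycan, at 36.5 ± 16.8 and 50.9 ± 16.2 CPM. The list value was low in ND 3, ND 4 and HCD 4, at -0.87, -0.99 and -0.78, against 0.064 to 0.71 in the other 5 libraries. The call was lost without ND 3, ND 4, HCD 1, HCD 2 or HCD 3 (adjusted p = 0.101, 0.165, 0.059, 0.0606 and 0.0762), and the list and Bgn turned down with the term for ND 2 to ND 4 (0.0954 for the list, median -0.29). The median was 0.882 without ND 1, where 1 gene passed over the list alone, 0.272 without ND 3, 0.27 without ND 4 and 0.322 without HCD 1.

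Endothelial genes were higher in 13 of 16 members, with a median of 0.24 (camera adjusted p = 0.0192, and adjusted p = 0.515 with an estimated correlation). Over the list alone and over all genes 0 passed, with 5 at an unadjusted p under 0.05 (edgeR; over the list alone DESeq2 passed 2 and limma-voom 0, and over all genes each called 0). Flt1, a receptor for vascular growth factors, was at 22.4 ± 1.39 CPM in ND and 27.7 ± 1.27 CPM in HCD, and Pecam1 at 23.7 ± 2.25 and 30.1 ± 2.49 CPM. The call was lost without ND 2, ND 4 or HCD 3 (adjusted p = 0.0519, 0.0953 and 0.096), and the list turned down with the term for ND 2 to ND 4 (0.824, median -0.07). The median was 0.121 without ND 4 and 0.117 without HCD 3. At a mean of at least 1 CPM 2 genes passed over the list alone, as 2 did with GC and length offsets. Pericyte and smooth muscle genes were higher in 6 of 9 members (camera adjusted p = 0.185), with 0 passing over the list alone or over all genes and 2 at an unadjusted p under 0.05 (edgeR; DESeq2 called 1 by both counts and limma-voom 0). Among them were Acta2 at 17.2 ± 5 and 29.2 ± 8.11 CPM and Cspg4 at 3.48 ± 0.85 and 5.10 ± 1.05 CPM. The list passed without ND 2 (0.0489), and 1 gene passed over the list alone without ND 2 or HCD 2.

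Skeletal muscle genes, which encode parts of muscle fibres, were lower in HCD in all 10 tested members, with a median log2 fold change of -1.92 (camera adjusted p = 2.09e-05, and adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 6 passed, and over all genes tested 0, with 8 at an unadjusted p under 0.05 (edgeR; DESeq2 passed 10 over the list alone and 3 over all genes, limma-voom 1 and 0). Ttn, titin, was at 3.85 ± 3.12 CPM in ND and 0.366 ± 0.271 CPM in HCD (log2 fold change -3.37), and Acta1, skeletal muscle actin, at 9.01 ± 8.57 and 0.552 ± 0.518 CPM (-4.01). The list value was 1.48 in ND 1, 2.08 in ND 2, 0.329 in ND 3 and -0.71 in ND 4, the last within the HCD range of -1.01 to -0.177. The count over the list alone was 2 without ND 2, 3 without HCD 2 and 3 with robust dispersion. The camera call held without ND 2 and without HCD 2, and camera was not run with robust dispersion. No count is given here for the term for ND 2 to ND 4, where ND 1 is the only ND library in the contrast. Adipocyte genes were higher in all 4 tested members (camera adjusted p = 0.0825), with 1, Fabp4, passing over the list alone at 8.17 ± 1.53 and 13.3 ± 4.26 CPM. Over all genes 0 adipocyte genes passed, with 1 at an unadjusted p under 0.05 (edgeR; DESeq2 and limma-voom 0). That list passed without HCD 4 (0.0103). Fabp4 no longer passed over the list alone without ND 1, ND 3, ND 4, HCD 1 or HCD 3, with the term, with GC and length offsets, at a mean of at least 1 CPM, or with DESeq2 size factors, upper-quartile factors or limma-voom. Red blood cell genes were higher in all 7 (camera adjusted p = 0.0864), with Slc4a1, an anion exchanger, at 3.46 ± 3.57 and 6.76 ± 5.46 CPM, and that list passed without ND 4 (0.00164, with 7 genes over the list alone), without HCD 2 (0.00531) and with the term (0.043). Without HCD 3, 5 red blood cell genes were higher and 2 lower, and the median fell from 0.946 to 0.273. Of 3 keratinocyte genes tested, 2 were lower (camera adjusted p = 0.1), with Sfn at 3.51 ± 0.764 and 2.31 ± 0.357 CPM, and the list passed without ND 2 (0.0489). Of the red blood cell and keratinocyte genes 0 passed over the list alone or over all genes by edgeR, DESeq2 or limma-voom, with 0 and 2 at an unadjusted p under 0.05 in edgeR. Over the list alone 1 keratinocyte gene passed without ND 2 and 2 without HCD 3.

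Of the 30 lists, 11 passed with the preset correlation. With an estimated correlation 0 passed, with 1 at an unadjusted p under 0.05, and by fry 0 passed, with 7 at an unadjusted p under 0.05. With no expression filter edgeR called, over all genes, 2 LXR target and 2 skeletal muscle genes. It also called 1 gene each of cholesterol synthesis, fatty acid synthesis and oxidative phosphorylation.

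**Figure D3:**
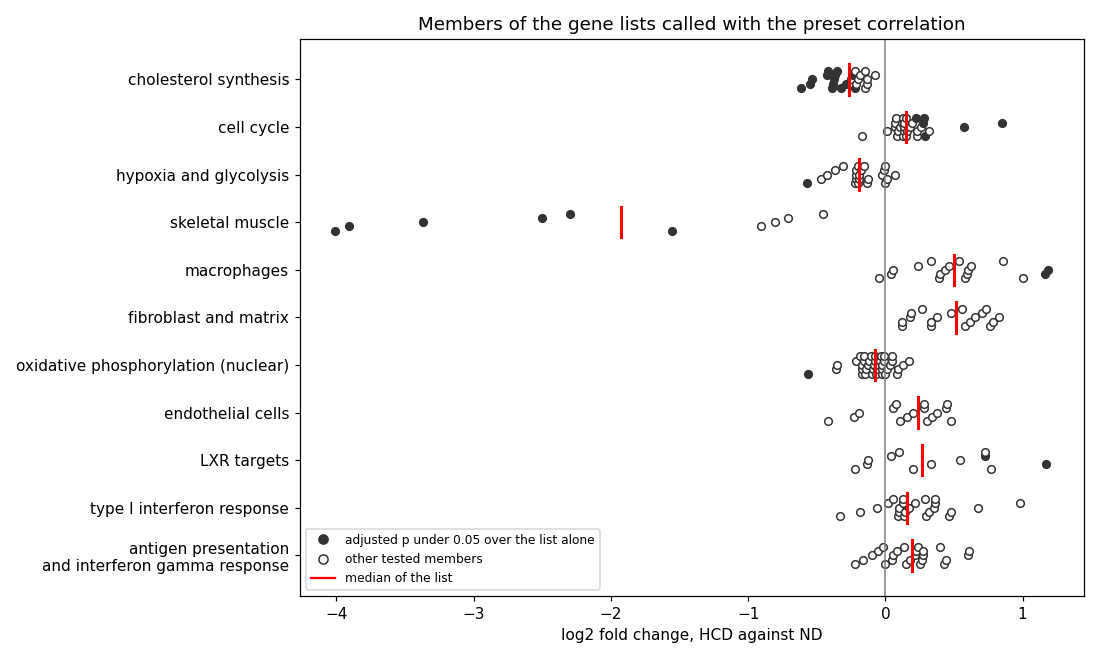
Log2 fold change, HCD against ND (horizontal axis), of each tested member of the 11 gene lists that passed camera with the preset correlation, 1 line of points per list. Filled points passed when adjusted over the list alone, open points are the other tested members and red bars are list medians, which run from -1.92 for skeletal muscle to 0.52 for fibroblast and matrix. All 24 cholesterol synthesis points lie below 0, and none of the 11 lists passed with an estimated correlation.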

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

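The tests of sequencing depth, of the diet as the source of the extra detected genes, and of both explanations for ND 2 were chosen after the result was seen. For the other tests the gene results, list values, detection and mitochondrial shares had been looked at before the tests were written down, so only each test's own value was unseen, and for the nuclear copies the fold changes it rests on were already known.

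A value was singled out where it lay farther from the other 3 libraries of its group than Dixon's test allows at the 95% level. This held for 29 of 384 groups of 4, against 19.2 by chance, with 16 in the HCD group, 5 in ND 1, 5 in ND 2, 2 in ND 3 and 1 in ND 4. Among called genes, HCD 2 was low for Rad54l (24.7 CPM, nearest 27.5) and Per2 (1.21, nearest 1.96) and high, toward the ND level, for Ndrg1 (260.2, nearest 232.8). Other genes were Ccne1 in ND 1 (56.3 CPM, nearest 48.4), Sox10 in HCD 3 (868.8, nearest 797.1), Per1 in HCD 1 (78.7, nearest 70.3) and Col1a2 in HCD 4 (18.5, nearest 77.2). Among immune genes, Entpd1 in HCD 1 (10.6 CPM, nearest 9.58), Vsir in HCD 3 (14.4, nearest 10.5), C1qc in HCD 3 (95.2, nearest 72.7), Mmp8 in ND 3 (5.99, nearest 1.596), Clec4d in ND 3 (4.82, nearest 1.43) and Itgae in ND 1 (0.858, nearest 0.370) were high. Low ones were Ccr2 in HCD 4 (3.12, nearest 3.92), Itgax in HCD 1 (10.5, nearest 11.8) and Oas2 in ND 2 (0.241, nearest 2.78). Muscle and red cell genes were Acta1 in HCD 3 (1.33 CPM, nearest 0.340), Myh4 in HCD 3 (0.692, nearest 0.0606) and Alas2 in ND 4 (109 CPM, nearest 23.1). List values were the mesenchymal (-0.22, nearest 0.175) and fibroblast (-0.78, nearest 0.547) lists in HCD 4, the cytotoxic (-1.68, nearest 0.215), interferon (-2.1, nearest 0.203) and ATF4 target (-0.0598, nearest 0.203) lists in ND 2, and the skeletal muscle list in HCD 3 (-0.18, nearest -0.99). Library measures were the number of detected genes in ND 1 (16745, nearest 18088), its genes with at least 10 counts (13412, nearest 13064), its receptor genes (11, nearest 438) and the mitochondrial share in ND 2 (14.7%, nearest 13.8%).

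ND 2, ND 3 and ND 4 detected more genes than ND 1 and the HCD libraries. Deeper sequencing is argued against, since the highest total of the 3 was 0.954 times the highest of the other 5, and after thinning to one total they kept 17881 to 18088 detected genes against 16091 to 16644. A candidate explanation is genomic DNA in the 3 libraries: the lowest number of olfactory and vomeronasal receptor genes among them was 33.7 times the highest among the other 5 (438 against 13). The diet stays open, because only ND 1 speaks against it, lying 79 times farther from the nearest ND library than from the nearest HCD library (1343 against 17 genes). With a term for the 3 libraries in edgeR, the log2 fold changes of the 24 called genes were 0.708 to 1.23 times those without it (median 0.937). The SE rose by a median of 1.58 times, and DESeq2 and limma-voom were not run with the term. That fit contrasts ND 1 with the HCD libraries, and the 24 genes were chosen with ND 1 already apart from every HCD value. Similar fold changes were therefore likely beforehand and do not speak against the 3 libraries as a source of the calls.

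The mitochondrial share of counts was lower in each HCD library than in each ND library, while the share on nuclear copies overlapped (two-sided exact permutation p = 0.0571, n = 4 each), with ND 1 at 0.884% within the HCD range of 0.719% to 0.944% and ND 2 to ND 4 at 1.16% to 1.25%. Whether reads on the 4 called copies come from the mitochondrial transcripts stays open. The copies are at least 99.793% identical to their parents, but each fell more than its parent, by 2.3 to 2.68 SE (differences from -0.34 to -0.24). These SE treat copy and parent as independent, although both come from the same libraries and may share reads, so the distances are not exact. A share of misplaced reads that differs between libraries was not tested. The lower mitochondrial share as the source of the other calls through scaling is argued against: without the mitochondrial genes and copies, 100% of the 20 other called genes stayed within 0.1 of their log2 fold change, with a largest shift of 0.0037 (Mitf 0.85, SE 0.112 before and 0.11 after). The call nevertheless ended for 16 of the 20, whose adjusted p moved from between 0.0459 and 0.0495 to between 0.0565 and 0.0568, a loss that had been set beforehand as a sign of scaling. It does not need scaling: with the p-values of the first fit kept and only adjusted anew without these genes, 17 of the 20 calls ended (adjusted p of the 16 from 0.0531 to 0.056), and the refit changed their p by 0.881 to 1.09 times.

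ND 2 was low in interferon and immune genes. Genomic DNA in this library is argued against, since 0 of the 2 other libraries with the extra genes, ND 3 and ND 4, had an interferon value below the other 5 (0.203 and 0.47 against 0.108 to 0.4). Fewer immune cells in the tumour piece and a lower interferon response cannot be told apart: interferon genes lay 0.69 further down than T cell genes (difference -0.69, SE 0.335), but 9 of the 10 T cell genes were under 1 CPM in ND 2, near the floor. By the first criterion this difference excluded fewer immune cells, and the floor criterion that left it open was added after the value was seen. Ptprc, a marker of all leukocytes, lay at -2.11 (2.47 CPM in ND 2). The macrophage genes, 1 of 18 under 1 CPM, lay at a median of -1.04 against -2.56 for interferon genes (difference -1.51, SE 0.259). Both SE are those of means over genes of ND 2, not over tumours. They treat the genes as independent, while estimated correlations were 0.944 in the interferon list and 0.405 in the macrophage list. Macrophage genes thus fell less than interferon genes in ND 2, but neither an equal nor an unequal loss of immune cells is excluded.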

How the results depend on the processing

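Robust dispersion, the threshold of 0.10, the term for ND 2 to ND 4, the fit without mitochondrial genes and copies and the GC and length offsets were chosen after the data were seen. Against 24 called genes (9 higher, 15 lower), the count was 0 (0 and 0) at an adjusted p under 0.01, 4 (1 and 3) with at least a 2-fold change, 156 (68 and 88) at 0.10, 428 (189 and 239) by DESeq2, 93 (38 and 55) with no filter, 42 (20 and 22) at a mean of at least 1 CPM, 0 (0 and 0) with the replicate block (edgeR, 1634 at an unadjusted p under 0.05), 50 (24 and 26) with robust dispersion, 5 (4 and 1) with the term, 4 (2 and 2) without mitochondrial genes and copies, and 16 (4 and 12) with GC and length offsets. Leaving out each library gave 0 to 12 genes (0 to 6 higher, 0 to 6 lower). Limma-voom gave 19, DESeq2 size factors 23 and upper-quartile factors 24. All 24 genes kept their direction in each setting that tested them, which their non-overlapping groups made near certain beforehand. DESeq2, no filter, the 1 CPM filter and robust dispersion kept all 24 calls, the block and the term 0. Of 30 lists 11 passed, 0 with an estimated correlation, 0 by fry, 6 to 14 with a library left out, 12 with the block and 5 with the term. Correlations of same-numbered libraries were 0.0249, -0.0113, -0.0676 and 0.107, with the own number highest for 1 of 4. They do not show that the replicate numbers pair the samples, but they cannot exclude shared handling, on which the labels are silent. The block turned the B cell list into a call (0.0448). Over the list alone it gave, among others, 9 cholesterol synthesis, 1 cell cycle and 4 macrophage genes, and inflammatory genes were 6 higher and 6 lower. Of 149 genes checked 25 changed sign in at least 1 setting, none of them called, and the cause was not tested. With the term these were Snai1 -0.17, Tnc -0.40, Col1a2 -0.26, Bgn -0.19, Loxl1 -0.066, Il2rb -0.25, Klrk1 -0.37, Lgals9 -0.17, Vsir -0.18, Mmp8 0.75, Clec4d 0.31, Itgae -0.0099, Oasl2 -0.0056, H2-K1 -0.068, H2-Ab1 -0.13, H2-Eb1 -0.17, Dsp -0.42, Cd8a -0.54 and Arntl 0.025. By limma-voom they were Prf1 0.19, Clec4d 0.020, Clec4e 0.11 and Il1b 0.15, and with the block Prf1 0.055. With a library left out the ranges, with the libraries whose absence changed the sign, were Lck -0.34 to 0.0038 (ND 3), Prf1 -0.54 to 0.15 (ND 1, ND 3), Tbx21 -0.44 to 0.61 (ND 2, ND 3, HCD 2) and Lgals9 -0.017 to 0.31 (ND 2). For Mmp8 they were -1.15 to 0.29, Clec4d -0.52 to 0.52 and Il1b -1.56 to 0.20 (ND 3 each), Dsp -0.10 to 0.65 (HCD 2), Lipe -0.0039 to 0.23 (HCD 1) and Cd8a -0.16 to 0.48 (ND 2). Called lists that turned down were fibroblast (adjusted p = 0.0954), endothelial (0.824), interferon (0.578) and antigen presentation (0.293) with the term, and interferon (0.122) and antigen presentation (0.0489) without ND 2, with ranges over libraries left out of 0.000585 to 0.122 and 0.000319 to 0.106. Pseudocounts were not varied in the gene test, since it ran on counts.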

Other observations

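All 7 lists described here were chosen after the data were seen, and the tests of clock phase and glucocorticoid signalling were written down before their own values but after the gene results. Adjusted p-values of these lists cover the 7 alone and not the 30 fixed lists. They are therefore more lenient and cannot be set beside those of the fixed lists. Targets of ATF4, the transcription factor of the integrated stress response, were lower in HCD in 28 of 29 members, 18 of them passing when adjusted over the list alone (camera adjusted p = 1.56e-12, adjusted p = 0.0903 with an estimated correlation, fry 0.00975). Of the 29, 8 stand in the lists fixed beforehand. Without the called Trib3 and Ddit3, 26 of 27 were lower (camera p = 2.81e-11, p = 0.0605 with an estimated correlation). Eif4ebp1, an inhibitor of translation initiation, was at 168 ± 10.2 CPM in ND and 134 ± 6.91 CPM in HCD (log2 fold change -0.32, adjusted p = 0.0857). DNA replication and repair genes were higher in 30 of 39 members, 10 over the list alone (camera adjusted p = 3.01e-06, adjusted p = 0.0249 with an estimated correlation, fry 0.000361), with 4 called members, Cdc6, Rad54l, Recql5 and Mlh3. Without these 4 the p was 0.000669, or 0.0201 with an estimated correlation. Because both lists were chosen after the called genes were seen, neither is independent evidence. Targets of the heat shock factor HSF1 were higher in 12 of 16 members (camera adjusted p = 0.00248, adjusted p = 0.21 with an estimated correlation, fry 0.0369), with 3 over the list alone, 4 of the 16 in the fixed lists, and Chordc1 and Ahsa1 at log2 fold changes of 0.45 and 0.32. Of 13 mitochondrially encoded genes 10 were lower, 5 over the list alone (camera adjusted p = 0.00514, adjusted p = 0.21 with an estimated correlation, fry 0.138), with mt-Co1 at 56320 ± 951 and 46320 ± 2930 CPM. The list values of the mitochondrially encoded genes overlapped, from -0.156 to 0.308 in ND and -0.25 to 0.256 in HCD (0.256 in HCD 4), as did those of the HSF1 targets (-0.162 to -0.00122 and -0.0213 to 0.232).

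Clock genes of the Per and Dbp phase were lower in HCD in 9 of 11 members, with 6 lower and 1 higher over the list alone (camera adjusted p = 9.31e-06, adjusted p = 0.0256 with an estimated correlation, fry 0.00117). Without Per2 the p was 8.36e-05, or 0.0127 with an estimated correlation. Cry2 was at 27.1 ± 0.931 CPM in ND and 18.1 ± 2.46 CPM in HCD, Dbp at 23.7 ± 1.24 and 16.1 ± 1.86 CPM, and Per1 at 93.1 ± 6.57 and 72.0 ± 4.44 CPM (adjusted p = 0.0638, 0.0653 and 0.0788). Clock genes of the Arntl phase were lower in 4 of 6 members (camera adjusted p = 0.183, adjusted p = 0.221 with an estimated correlation, fry 0.0369), 1 of them over the list alone, with Arntl at a log2 fold change of -0.41 that became 0.025 with the term for ND 2 to ND 4, and Cry1 at -0.35. A different phase of the clock at harvest was predicted to raise the genes of the opposite phase. Their median over the 4 genes tested was -0.30, 1 higher and 3 lower, which goes against that prediction. The SE of 0.139 is that of a mean over the 4 genes, not over tumours, and Arntl moved to 0.025 with the term. A different phase is therefore not excluded. Lower glucocorticoid signalling is a candidate for part of the fall of Per2, but its effect on Per2 was not tested. Without Sgk1 and Per1, 10 of 12 glucocorticoid targets were lower, with a median of -0.18 and camera p = 0.00201, but p = 0.0755 with an estimated correlation. The 2 higher ones, Fkbp5 and Dusp1 (log2 fold changes 0.049 and 0.12), were not carried through the alternatives. The whole list of 14 had 12 lower members, 6 over the list alone and 2 in the fixed lists (camera adjusted p = 5.16e-05, adjusted p = 0.0903 with an estimated correlation, fry 0.0108), and without Sgk1 the p was 0.000348, or 0.0648 with an estimated correlation. Time of harvest and hormone levels are not given in the sources used here.

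Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 24 called genes. That 1 of 35 is the lowest share possible, and the highest of the other splits gave 3. Every other split mixes ND and HCD libraries, so a diet difference would add to its spread and lower its count. The splits therefore rank the real one first but do not exclude chance. The ranking also does not separate the diet from the library differences that go with it. At an unadjusted p under 0.05 the highest of the other splits had 1334 genes, against 1939 for the real one.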
